A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

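RNA levels were measured on 1-colour Affymetrix arrays in 13 samples of Saccharomyces cerevisiae from glucose-limited, micro-aerobic chemostats with furfural in the feed, per the labels' protocols. Furfural is a growth-inhibiting aldehyde released when plant biomass is broken down. TMB3400 is the parent strain and TMB3400-FT30-3, called FT30-3 here, was adapted from it to high furfural. The groups were TMB3400 at 15 mM (n = 2) and 25 mM (n = 3), and FT30-3 at 15 mM (n = 3), 25 mM (n = 2) and 36 mM (n = 3). The series' design text calls the replicates biological. Total RNA was reverse-transcribed and labelled with biotin, per the labels' protocols.

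The values deposited by the authors are intensities on a linear scale, 1 per probe set and array. R 2.7.2 is named in the submitters' processing notes. The summary method, background correction and normalization are not given in the sources used here, so the values were used as deposited, and how the arrays were scaled or centred is unknown. The table holds 10928 probe sets. The platform annotation gave 1 S. cerevisiae gene for 5498 of them, 1 gene of another yeast, Schizosaccharomyces pombe, for 1746, several genes for 1, and none for 3683, of which 213 are control probe sets. Symbols were updated through gene identifiers. Chromosomes were read from systematic gene names, and no coordinates are given because the array's build is not given in the sources used here. YKL071W has no probe set of that name in the annotation used and was not analysed here.

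Tests used log2(intensity + 1), which understates changes of dim genes. One mean per strain and dose was fitted to all 13 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment within each comparison over probe sets and a threshold of 0.05. A gene with several probe sets (47 genes) was represented by the brightest, giving 5449 genes. Only 1 of these 47 genes had probe sets called in opposite directions, in the comparison of 25 with 15 mM in FT30-3. The comparisons were FT30-3 against TMB3400 at 15 mM, at 25 mM and averaged over both, 25 against 15 mM in each strain, 36 against 15 mM and 36 against 25 mM in FT30-3, and the strain by dose interaction. Before the data were examined, 42 gene lists were fixed and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists.

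The genes named were chosen by a rule fixed before the data were examined. It took the 10 highest and 10 lowest log2 changes among called genes, up to 4 members with the smallest p of each list described and, in strain comparisons, ADH6, ADH7, ARI1, GRE2, GRE3, ZWF1, GND1, TKL1, TAL1, ALD6, XKS1, PDR5 and YKL071W. Some of these, such as ADH7 and ARI1, may have been picked by the study on these samples and are then not independent evidence. Members of near-identical families (the HXT, PAU and YAR066W/YAR068W families) may share signal and their values are uncertain. Not all genes chosen by the rule are named below, and the rule did not set which were left out.

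S. pombe probe sets have no target in these cultures and served as background, and were tested in a fit of their own with their own adjustment. Their 95th percentile lay between 31.2 and 39 on the 13 arrays, against medians of 1412 to 1663 for S. cerevisiae probe sets. A gene at or below that percentile on every array of a group has only a bound there, and its fold is given as at least the ratio to the background. The number of arrays limits the precision. Replicate arrays correlated across probe sets at r = 0.966 to 0.995 in FT30-3 at 36 mM and at 0.985 to 0.994 in the other groups. No arrays held identical values.

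The median log2 change of all genes was 0.13 for 25 against 15 mM in TMB3400, 0.13 in FT30-3 and 0.17 for 36 against 15 mM. Changes with dose are therefore given from the same fit after setting each array's median to a common value.

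The procedure was tested on simulated data with 200 changed genes over 5498 probe sets. For the strain difference at 15 mM it recovered 42.6% of 1.5-fold, 82.8% of 2-fold and 98.5% of 4-fold changes. For 36 against 15 mM the shares were 64.7%, 92.2% and 100%, and for the interaction 20.6%, 57.8% and 94.1%. In a separate simulation of the strain difference at 15 mM over 5449 genes, camera called the proteasome list, shifted by 0.3, and 0 of the others among the 42 lists. These simulations have independent genes and do not cover correlated lists or differences between sets of arrays. Alternatives covered normalization, centring, filters, the variance model, array weights, the samples fitted, a replicate block, a fold threshold, the pseudocount, the list test and leaving out each sample. A filter at mean log2 of 9, leaving out chromosome XVI, fitting S. pombe probe sets together with the genes, the overlap of S. pombe calls and fits of the 4 groups other than FT30-3 at 15 mM, with and without a replicate block, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.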

Results

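Array intensities of 5449 S. cerevisiae genes were compared between an evolved furfural-resistant strain, FT30-3, and its parent, TMB3400, and between feed furfural levels of 15, 25 and 36 mM. TMB3400 washed out at 36 mM, so that level holds FT30-3 only. The series' title concerns NADPH-dependent reduction of furfural by oxidoreductases. Changes are log2 values ± standard error with adjusted p from limma, and intensities are mean ± SD.

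At 15 mM, FT30-3 differed from its parent in 125 of 5449 genes, 114 higher and 11 lower. Of the 114 higher genes, 108 lie on chromosome XVI, which holds 424 of the genes measured, and 0 of the 11 lower genes do. They included EEB1, an enzyme of ethyl ester synthesis (1.23 ± 0.18, adjusted p = 0.0061), the mitotic cyclin CLB2 (1.10 ± 0.14, adjusted p = 0.00403), FRK1 (1.05 ± 0.12, adjusted p = 0.00284) and SGF11 (0.96 ± 0.10, adjusted p = 0.0022). The lowest values were those of FLO11, a cell-surface flocculin (-4.50 ± 0.58, adjusted p = 0.00345), and FET4, a low-affinity iron transporter (-3.80 ± 0.35, adjusted p = 0.0014). FLO11 had an intensity of 5362 ± 2330 (n = 2) in TMB3400 and 265.4 ± 191 (n = 3) in FT30-3, and FET4 had 1642 ± 381 and 117.1 ± 26.6. YAR068W (-2.36 ± 0.24) and YAR066W (-1.93 ± 0.19) were also lower, with adjusted p of 0.0017 and 0.0014. The count was 7 without TMB3400 at 15 mM replicate 2, 27 without its replicate 1, 49, 41 and 37 without FT30-3 at 15 mM replicates 1, 2 and 3, 258 without FT30-3 at 36 mM replicate 1, and 5 without chromosome XVI. Without TMB3400 at 15 mM replicate 2, FLO11, EEB1 and CLB2 no longer passed (adjusted p = 0.0755, 0.114 and 0.0755, the highest over all alternatives, whose lowest were 0.000452, 0.000713 and 0.000456).

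Chromosome XVI was singled out after its values were seen, so no test of its shift was independent of these arrays. The median log2 strain difference of chromosome XVI exceeded that of the other chromosomes by 0.47 at both 15 and 25 mM, a ratio of 1.39 at 15 mM. The largest difference of any other chromosome was 0.06 at both levels. With dose, the chromosome XVI difference was 0.008 in TMB3400 and -0.015 in FT30-3 for 25 against 15 mM. In each sample, an index of chromosome XVI against the other chromosomes lay between 0.15 and 0.21 in the 8 FT30-3 samples and between -0.30 and -0.27 in the 5 TMB3400 samples.

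**Figure D1:**
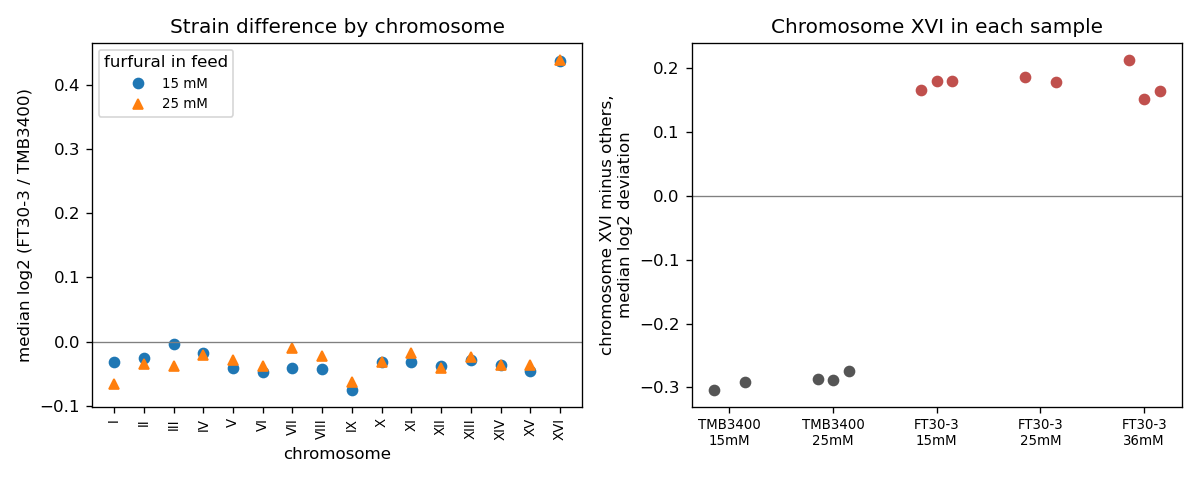
Left, the median log2 ratio of FT30-3 to TMB3400 for the genes of each chromosome at 15 mM (circles) and 25 mM (triangles). Right, points are samples, and the vertical axis is the median log2 deviation of chromosome XVI genes from their mean over all samples minus that of the other chromosomes, between 0.15 and 0.21 in FT30-3 and between -0.30 and -0.27 in TMB3400.

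At 25 mM, 338 genes differed between the strains, 238 higher and 100 lower in FT30-3, and 147 of the 238 lie on chromosome XVI. ADH7, an NADPH-dependent alcohol dehydrogenase, was higher by 3.01 ± 0.59 (adjusted p = 0.0113), with 10760 ± 3610 (n = 2) in FT30-3 against 1759 ± 1670 (n = 3) in TMB3400. ARI1, an NADPH-dependent aldehyde reductase, was higher by 1.34 ± 0.33 (adjusted p = 0.0362). ADH6, a relative of ADH7, was lower by 0.50 on the log2 scale in FT30-3 (-0.50 ± 0.11, adjusted p = 0.0231). FET4 (-4.81 ± 0.35, adjusted p = 1.2e-05), FLO11 (-3.77 ± 0.58, adjusted p = 0.00315) and YAR068W (-2.65 ± 0.24, adjusted p = 8.98e-05) were lower here too. FET4 read 52.29 and 37.62 in FT30-3 at 25 mM replicates 1 and 2. Background on these arrays was 32.9 and 32.3, so the size of the FET4 difference is uncertain and not shown to exceed that at 15 mM. HXT3, a low-affinity glucose transporter, was 2.09 ± 0.10 higher in FT30-3 (adjusted p = 2.51e-07). The count was 121 without FT30-3 at 25 mM replicate 1, 221 without TMB3400 at 25 mM replicate 2 and 584 without FT30-3 at 36 mM replicate 1. Without FT30-3 at 25 mM replicate 1, ADH7 (adjusted p = 0.128), ARI1 (0.236) and ADH6 (0.17) did not pass, and over all alternatives their adjusted p ran from 0.000243, 0.0214 and 0.00733 up to these values. ADH6 also lost its call without FT30-3 at 25 mM replicate 2 (0.0735) and without TMB3400 at 25 mM replicate 1 (0.0785) or 3 (0.0727), and in a fit of the 4 groups other than FT30-3 at 15 mM, with the replicate number as a block (0.0576) or without it (0.052). ARI1 lost its call in that fit without the block (0.0733). ARI1 also lost its call without FT30-3 at 25 mM replicate 2 (0.109), and narrowly (0.0509 to 0.0563) without TMB3400 at 15 mM replicate 1 or 2, FT30-3 at 15 mM replicate 2 or 3, TMB3400 at 25 mM replicate 3 or FT30-3 at 36 mM replicate 3. In this comparison 134 of the 1746 S. pombe probe sets (7.67%), which have no target here, also passed in limma, a larger share than of genes (6.2%). At 15 mM 0 passed in limma, where 74 had an unadjusted p under 0.05 and 5 passed when fitted and adjusted together with the genes. Those 74 are no larger a share than the 0.05 that chance alone gives, while 359 were under 0.05 at 25 mM. Small dim genes such as YJL136W-A (at least 6.68-fold higher) and YNL067W-B (at least 5.6-fold higher) are among the 10 highest at 25 mM. YPL038W-A (4.021, adjusted p = 4.63e-10) is also among those 10.

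ADH7 and ARI1 did not pass between the strains at 15 mM (1.32 ± 0.59, adjusted p = 0.411, and 0.22 ± 0.33, adjusted p = 0.86). Their strain difference was not shown to depend on dose, since the interaction was 1.69 ± 0.84 for ADH7 and 1.12 ± 0.47 for ARI1, each with an adjusted p of 1.

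The 2 strain comparisons shared 94 higher genes where 4.98 are expected of independent lists, and 6 lower genes where 0.202 are. Only 6 of the 114 higher genes at 15 mM lie off chromosome XVI, so nearly all shared higher genes lie on it. The shift of that chromosome alone would make the higher lists overlap, so their excess is not evidence gene by gene. The 2 comparisons have no arrays in common, but both use the spread estimated from all 13 arrays. Averaged over both levels, 586 genes differed, 390 higher, of which 258 lie on chromosome XVI, and 196 lower. ADH7 was higher by 2.17 ± 0.42 (adjusted p = 0.00675) and FDH1, a formate dehydrogenase, by 1.48 ± 0.24 (adjusted p = 0.00278). ADH6 (-0.41 ± 0.08, adjusted p = 0.00615), the xylulokinase XKS1 (-0.40 ± 0.08, adjusted p = 0.0115) and the chaperone SSA2 (-1.09 ± 0.21, adjusted p = 0.00621) were lower. XKS1 lost its call without TMB3400 at 15 mM replicate 1 (adjusted p = 0.052; 0.00159 to 0.052 over the alternatives). Of 24 alternatives each, ARI1 passed in 6 (lowest adjusted p = 0.0265), GRE2 in 4 (0.0214) and PDR5 in 3 (0.0401), and the highest adjusted p were 0.171, 0.206 and 0.36. These included leaving out FT30-3 at 36 mM replicate 1 for ARI1 and GRE2, and TMB3400 at 25 mM replicate 1 or 2 for ARI1. ARI1 (0.78 ± 0.23, adjusted p = 0.0587), GRE2 (0.28 ± 0.08, adjusted p = 0.0603), GRE3 (-0.06 ± 0.11, adjusted p = 0.788) and PDR5 (0.15 ± 0.06, adjusted p = 0.133) did not pass. Nor did the pentose phosphate and acetate genes ZWF1 (-0.10), GND1 (-0.11), TKL1 (0.04), TAL1 (-0.05) and ALD6 (0.09). Of these, TKL1 and ALD6 lie on chromosome XVI, so their values are low for that chromosome. Its genes had a median of 0.446 in this comparison, with 96.7% above 0. Of 13 pentose phosphate pathway genes, 12 had values below 0, but 1 fell in limma, GND2 (-0.26 ± 0.07, adjusted p = 0.043), and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. GND2 lost its call in 14 of 24 alternatives (adjusted p = 0.0192 to 0.163), among them leaving out any 1 of the samples at 15 or 25 mM, or FT30-3 at 36 mM replicate 2. The list's adjusted p was 0.0102 with the preset correlation of camera, 0.0094 with fry, and adjusted p = 0.72 with an estimated correlation. Leaving out TMB3400 at 15 mM replicate 1 or 2 gave 341 or 349 genes, and leaving out FT30-3 at 36 mM replicate 1 gave 985.

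**Figure D2:**
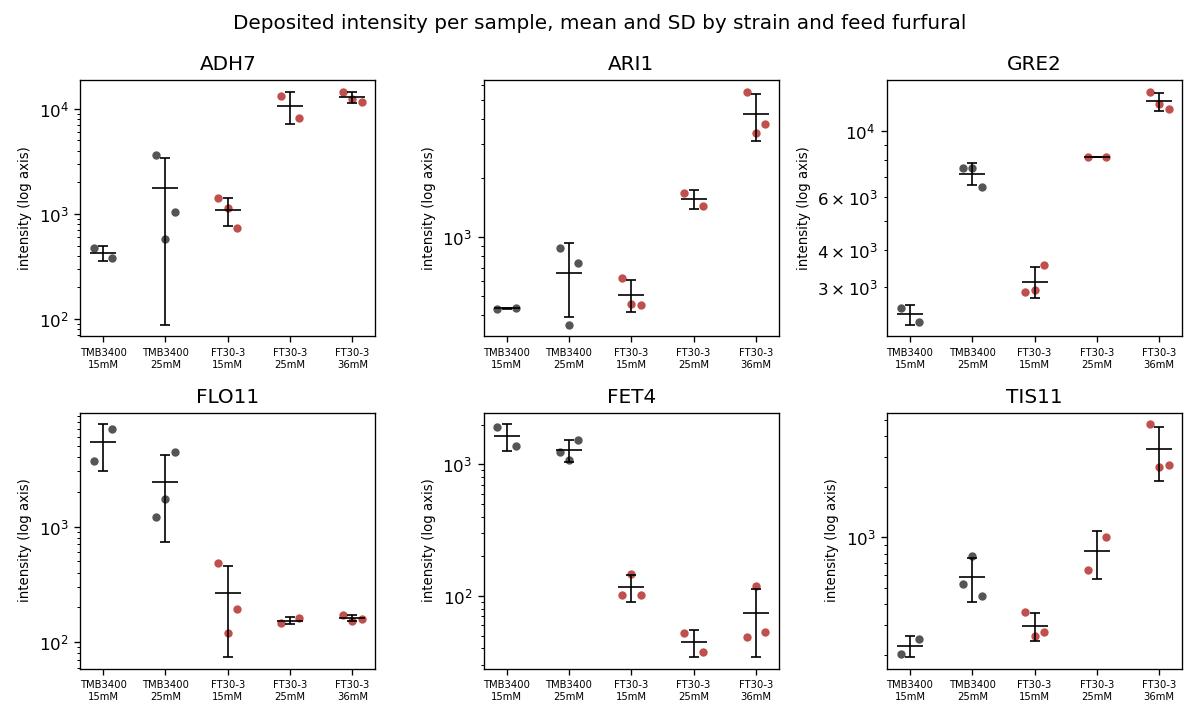
Deposited intensity (log axis) of 6 genes in each sample by strain and feed furfural, with points for samples and bars for the mean and SD (n = 2 or 3). ADH7 averaged 426 in TMB3400 at 15 mM and 12860 in FT30-3 at 36 mM, and FET4 averaged 1642 and 73.95 in the same groups.

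The next question was what changed when the feed rose from 15 to 25 mM. In TMB3400, 156 genes passed, 120 higher and 36 lower, and after centring 89 passed, 44 higher and 45 lower. The reductase gene GRE2 rose by 1.43 ± 0.12 (adjusted p = 6.13e-05), from an intensity of 2426 ± 184 (n = 2) to 7207 ± 601 (n = 3), and the NADPH dehydrogenase gene OYE3 by 1.07 ± 0.12 (adjusted p = 0.000761). ARN1 and ENB1, transporters of iron-siderophore complexes, rose by 1.34 ± 0.23 (adjusted p = 0.0112) and 1.18 ± 0.22 (adjusted p = 0.0215). EMI1 rose by 3.52 ± 0.27 (adjusted p = 2.92e-05) and GYL1 by 1.80 ± 0.12 (adjusted p = 8.61e-06). HXT3 fell by 2.34 on the log2 scale (adjusted p = 2.51e-07). The largest fall before centring was that of YPL038W-A (-3.545, adjusted p = 1.84e-09). Of 28 iron and copper genes, 4 rose and 1 fell after centring, and before it 11 rose and 1 fell, or 12 and 1 adjusted over the list alone. The list had an adjusted p of 0.000312 with the preset correlation and an adjusted p = 0.45 with an estimated correlation. Before centring, 36 and 42 genes passed without TMB3400 at 15 mM replicates 1 and 2, 88, 74 and 81 without TMB3400 at 25 mM replicates 1, 2 and 3, 100 without FT30-3 at 15 mM replicate 3 and 367 without FT30-3 at 36 mM replicate 1. ARN1 and ENB1 did not pass without TMB3400 at 15 mM replicate 1 (adjusted p = 0.073 and 0.146, the highest over the alternatives, whose lowest were 0.000205 and 0.00227). In this comparison 76 S. pombe probe sets passed (4.35%), against 2.86% of genes, before centring.

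In FT30-3 the same step changed 204 genes, 167 higher and 37 lower, and after centring 117, 67 higher and 50 lower. ADH7 rose by 3.14 ± 0.59 (adjusted p = 0.0156), ARI1 by 1.47 ± 0.32 (adjusted p = 0.0394) and GRE2 by 1.24 ± 0.12 (adjusted p = 0.000184). The sulfiredoxin gene SRX1 rose by 0.99 ± 0.20 (adjusted p = 0.029), and the glutathione transferase gene GTT2 by 0.89 ± 0.13 (adjusted p = 0.00415). The largest rise before centring was that of YNL067W-B (3.523) and the largest fall that of YLR162W (-3.102). Both were at background in at least 1 group compared in the interaction, so these values are uncertain. EMI1 (3.371) and PDR18 (-2.202) also passed before centring. Of 20 aldehyde reductase genes, 4 rose after centring, and before it 5 rose, or 8 adjusted over the list alone. Some members may have been picked by the study on these samples, so the list is not independent evidence. The list's adjusted p was 0.0068, and its adjusted p = 0.76 with an estimated correlation. Before centring, the count was 85 and 114 without FT30-3 at 25 mM replicates 1 and 2, 100 and 98 without FT30-3 at 15 mM replicates 2 and 3, and 440 without FT30-3 at 36 mM replicate 1. ADH7, ARI1 and SRX1 did not pass without FT30-3 at 25 mM replicate 1 (adjusted p = 0.118, 0.166 and 0.15, the highest over the alternatives, whose lowest were 0.000301, 0.00161 and 0.00901). ARI1 also lost its call without FT30-3 at 25 mM replicate 2 (0.0767) or FT30-3 at 15 mM replicate 2 (0.0748) or 3 (0.0789), and SRX1 without the last of these (0.0525). In this comparison 150 S. pombe probe sets passed (8.59%), against 3.74% of genes, before centring. After centring, the strains shared 27 genes that rose with this step and 9 that fell, where 0.541 and 0.413 are expected of independent lists. S. pombe probe sets, centred by the same medians of S. cerevisiae probe sets, shared 7 higher and 24 lower, where 0.521 and 3.85 are expected. This centring moves S. pombe values down with dose, but before it they also shared 10 and 19, where 0.817 and 2.68 are expected. The excess among genes is therefore not shown to be a shared response.

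At 36 against 15 mM, 1752 genes passed in FT30-3, 1494 higher and 258 lower, and after centring 1213 passed, 601 higher and 612 lower. The largest rises included TIS11, which acts in messenger RNA decay under iron shortage (3.24 ± 0.27, adjusted p = 2.54e-05). The siderophore transporter gene ARN1 rose by 2.98 ± 0.20 (adjusted p = 5.91e-06), ENB1 by 2.77 ± 0.20 (adjusted p = 8.58e-06) and ARN2 by 2.39 ± 0.16 (adjusted p = 4.42e-06). ADH7 rose by 3.40 ± 0.52 (adjusted p = 0.0012), ARI1 by 2.84 ± 0.29 (adjusted p = 9.82e-05) and GRE2 by 1.82 ± 0.11 (adjusted p = 2.57e-06). The intensity of ARI1 was 509.1 ± 94.6 at 15 mM and 4238 ± 1140 at 36 mM (n = 3 each). YBR090C rose at least 59.6-fold before centring, from background. The sulfate transporter gene SUL1 fell by 3.14 on the log2 scale (adjusted p = 0.000669), the amino acid permease gene GAP1 by 2.54 (adjusted p = 0.000602) and the phosphate transporter gene PHO84 by 2.48 (adjusted p = 0.000999). The aquaporin gene AQY1 fell by 3.55 (adjusted p = 0.000262) and PHM7 by 3.74 (adjusted p = 0.000128). Before centring the largest fall was that of HXT15 (-3.906, adjusted p = 0.000318).

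Among the lists fixed in advance, 17 of 28 iron and copper genes rose and 3 fell after centring (20 and 3 adjusted over the list alone, before centring; adjusted p = 0.18 with an estimated correlation). Of 33 proteasome genes, 20 rose after centring and 30 before it (31 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), including RPT6 (0.81 ± 0.11) and the transcription factor gene RPN4 (0.61 ± 0.09), with centred adjusted p of 0.000602 and 0.000801. Of 25 heat shock and chaperone genes, 10 rose after centring (18 adjusted over the list alone, before centring; adjusted p = 0.5 with an estimated correlation), among them SSA2 (1.86 ± 0.26, adjusted p = 0.000671) and HSP82 (1.17 ± 0.23, adjusted p = 0.00515). Of 20 genes of gluconeogenesis, the glyoxylate cycle and C2 use, 14 fell after centring (14 adjusted over the list alone, before centring; adjusted p = 0.18 with an estimated correlation), including MLS1 (-1.99 ± 0.27, adjusted p = 0.000622) and FBP1 (-1.91 ± 0.24, adjusted p = 0.000383). Of 30 mitochondrial ribosome genes, 20 fell after centring and 7 before it (5 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). With the preset correlation, the adjusted p of these 5 lists from camera were 0.000164, 1.58e-09, 0.00269, 6.3e-12 and 1.37e-11, in that order. In this comparison 110 S. pombe probe sets passed (6.3%), against 32.2% of genes, before centring.

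Between 25 and 36 mM, 364 genes passed, 222 higher and 142 lower, and after centring 388, 185 higher and 203 lower. ARN2 rose by 1.75 ± 0.17 (adjusted p = 0.000196), ENB1 by 1.66 ± 0.22 (adjusted p = 0.0017) and TIS11 by 1.96 ± 0.30 (adjusted p = 0.0035), although TIS11 did not pass without FT30-3 at 25 mM replicate 1 (adjusted p = 0.0503, before centring; 0.00195 to 0.0504 over the alternatives). GAP1 fell by 2.54 on the log2 scale (adjusted p = 0.00294), PHM7 by 3.04 (adjusted p = 0.00244) and FBP1 by 1.74 (adjusted p = 0.00346), although FBP1 did not pass with only the groups compared in the fit (adjusted p = 0.0703, before centring; 0.00158 to 0.0703 over the alternatives). Of the 20 genes of gluconeogenesis, the glyoxylate cycle and C2 use, 14 fell after centring (15 adjusted over the list alone, before centring; adjusted p = 2.55e-12 with the preset correlation, and adjusted p = 0.41 with an estimated correlation). Without FT30-3 at 25 mM replicates 1 and 2 the counts before centring were 119 and 188. In this comparison 90 S. pombe probe sets passed (5.15%), against 6.68% of genes, before centring.

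The strain by dose interaction passed for 37 genes, 23 higher and 14 lower. HXT3 had an intensity of 1150 ± 79.1 in TMB3400 at 25 mM (n = 3), against group means of 4909 to 5288 in the other 4 groups (interaction 2.10 ± 0.13, adjusted p = 9.89e-06). MTR4, an RNA helicase gene, had 1107 ± 120 in FT30-3 at 25 mM (n = 2), against 2887 at 36 mM and 2923 at 15 mM in that strain (interaction -1.38 ± 0.17, adjusted p = 0.00207). The count was 23 and 22 without TMB3400 at 15 mM replicates 1 and 2. In this comparison 25 S. pombe probe sets passed (1.43%), against 0.679% of genes. Of the 37 genes, 20 are among the 861 genes with a mean log2 intensity under 9.

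Camera called 11, 14 and 12 of the 42 lists in the strain comparisons at 15 mM, 25 mM and averaged. It called 16 and 12 for 25 against 15 mM in TMB3400 and FT30-3, 17 for 36 against 15 mM, 14 for 36 against 25 mM and 6 for the interaction. With an estimated correlation it called 0 in every comparison, the smallest adjusted p being 0.18 for 36 against 15 mM and 0.93 for the strains at 15 mM. In the same order of comparisons, 0, 0, 1, 3, 5, 7, 4 and 1 lists had an unadjusted p under 0.05 with it, and fry called 0, 4, 5, 7, 7, 23, 8 and 0. Fry was run before centring and tests a list against no change, not against the other genes. Its dose calls may therefore include lists that only follow the general rise, a median of 0.13 to 0.17 against 15 mM. For the mean strain difference, 42 of 100 splits of the samples gave at least as many list calls with the preset correlation as the real groups.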

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

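All tests of the S. pombe probe sets and of the scaling, and the test of chromosome XVI against sets of arrays, were chosen only after the result was seen. The tests by brightness and along chromosome XVI were chosen before their own results were seen, but after the shift of that chromosome was.

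Probe sets of S. pombe, which no comparison used, differed between groups. They were called 134 times between the strains at 25 mM, 38 on average, 76 and 150 for 25 against 15 mM in TMB3400 and FT30-3, 110 for 36 against 15 mM, 90 for 36 against 25 mM and 25 in the interaction, but 0 times between the strains at 15 mM by limma, where 74 had an unadjusted p under 0.05 and 5 passed when fitted together with the genes. Between the strains at 25 mM, 359 had an unadjusted p under 0.05. Across S. pombe probe sets, arrays of both strains at 15 mM correlated at a median r of 0.65 and those at 25 mM at 0.38, a difference of 0.27, which is consistent with arrays hybridised or processed in separate sets. S. pombe RNA in some samples would move them 1 way, and 69.3% of those called in FT30-3 at 25 mM moved in the commoner direction, which argues against it as the whole source. Cross-hybridisation of S. cerevisiae RNA that changed with dose stays open, with 0 calls at 15 mM deciding nothing. With such sets, set and group cannot be told apart in the comparisons other than the strains at 15 mM, and p-values there may be too small.

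Genes of chromosome XVI were higher in FT30-3. Separate sets of arrays would leave no shift between the strains at 15 mM, where it was 0.471. Brightness would remove it among genes of like intensity, where the smallest difference at 15 mM was 0.403 in 3 classes. As a hypothesis, FT30-3 may carry an additional copy of the whole chromosome: 100% of 405 windows of 20 neighbouring genes had a median above 0.2, and the arms had medians of 0.45 and 0.41. The windows overlap and use the values that prompted the hypothesis, 97.6% of which were above 0, so this outcome was nearly given. They show that the shift ran along the whole chromosome, and do not test its cause. No DNA measurement was analysed here, and gene regulation over the whole chromosome stays open as untested.

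More genes were higher than lower at 36 against 15 mM, and centring evened the split. If the scaling of the arrays were the cause, added bacterial control transcripts would rise with the median of all genes. They changed by -0.202 ± 0.167 (SE), below 0 by more than 1 standard error, the first bound set, which would have excluded scaling, but not by 2, a bound put in its place after this value was seen. The median S. pombe intensity was also lower on the 3 arrays at 36 mM (9.97 to 10.5) than on the 3 at 15 mM (10.9 to 11.2), against a median rise of 0.17 for genes. Both go against scaling as the whole cause, but scaling and a general rise cannot be told apart, since the choice of bound decides the first, which also depends on the amount added, and the second lies near background and differs between sets of arrays.

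A control probe set for the 5′ part of the 25S ribosomal RNA read 6656 to 8979 in the 5 FT30-3 samples at 25 and 36 mM and 78.8 to 159 in the other 8 samples, a ratio of medians of 68.5. In each of the 7 other 25S probe sets the values of these 5 and 8 samples overlapped, with ratios of medians from 0.883 to 1.7.

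The strain by dose interaction, a test of the difference itself, passed for the genes that follow, as log2 values. Higher were YIR018C-A (3.88), YPL038W-A (3.58), YNL067W-B (3.49), YJL136W-A (3.13), HUR1 (2.46), YHR050W-A (2.14), HXT3 (2.10), YAR066W (2.00), SPO13 (1.91), MDJ2 (1.80) and REC8 (1.69). Lower were YNL042W-B (-4.66), YHL048C-A (-3.09), YLR162W (-2.70), PDR18 (-2.60), YGR153W (-2.51), SAP1 (-1.80), YER078W-A (-1.79), SOV1 (-1.72), MNT2 (-1.71) and MTR4 (-1.38). YNL067W-B, YJL136W-A, SPO13, MDJ2, YNL042W-B, YHL048C-A and YLR162W were at background in at least 1 of the groups compared, so their values come from the fit and are neither exact nor bounds. Some calls were fragile: the call was lost in 17 of 23 alternatives for YJL136W-A (adjusted p up to 0.289), 14 of 23 for YER078W-A (0.199), 13 of 23 for YNL042W-B (0.199), 11 of 23 for YHR050W-A (0.191) and 6 of 24 for YGR153W (0.111). The first 4 of these each had their highest adjusted p without TMB3400 at 15 mM replicate 2, and YGR153W without replicate 1 of that group. Their lowest adjusted p, in the same order, were 0.0016, 0.00087, 0.00276, 0.0232 and 0.00313. The 6 lists called had an adjusted p of 0.00847 for the respiratory chain, 0.0491 for sulfur and methionine, 0.000663 for branched-chain and other amino acids, 0.00294 for purine and one-carbon, 0.000152 for meiosis and sporulation and 1.75e-05 for cytosolic ribosomal proteins. With an estimated correlation the smallest adjusted p of any list was 0.92.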

How the results depend on the processing

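The filter at mean log2 of 9, the joint fit with S. pombe probe sets, the fits of 4 groups, the fits without chromosome XVI and the division of same-number pairs by group were chosen only after the result was seen. Numbers of genes moved by more than 1.5 times in these cases. Array weights gave 443 genes for the strains at 15 mM, 887 for their mean difference, 836 for 25 against 15 mM in TMB3400, 2998 for 36 against 15 mM and 59 for the interaction. The weights did not converge (0.11 for FT30-3 at 36 mM replicate 1, 5.22 for replicate 2), so these counts are unreliable. Requiring a 2-fold change gave 10, 82 and 35 for the strains at 15 mM, 25 mM and on average, 50 and 76 for 25 against 15 mM in TMB3400 and FT30-3, 202 for 36 against 15 mM and 100 for 36 against 25 mM, by its construction. Without chromosome XVI the strain comparisons gave 5, 129 and 200. With only the groups compared in the fit, the counts were 188 for the strains at 25 mM, 81 and 125 for 25 against 15 mM in TMB3400 and FT30-3, and 70 for 36 against 25 mM, from fewer samples. Quantile normalization gave 87 and 120 for 25 against 15 mM in TMB3400 and FT30-3 and 1113 for 36 against 15 mM, and median centring gave 89 and 117 for the first 2 of these. Without probe sets under mean log2 of 9, 121 genes passed for 25 against 15 mM in FT30-3 and 16 for the interaction. Where no reason is given, the cause was not tested.

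In 1 fit and adjustment over both species, the shares of S. pombe probe sets and of genes called were 0.286% and 0.991% for the strains at 15 mM, 8.42% and 5.36% at 25 mM and 5.56% and 8.39% on average. They were 4.47% and 2.13% for 25 against 15 mM in TMB3400, 7.96% and 3.19% in FT30-3, 12.1% and 27.1% for 36 against 15 mM, 5.27% and 4.92% for 36 against 25 mM, where the separate fits gave the larger share to genes, and 1.66% and 0.606% for the interaction. That fit called 54 genes for the strains at 15 mM, against 125.

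Lists moved as follows. Camera with an estimated correlation called 0 in all 8 comparisons. Fry, which tests whether a list's genes move 1 way on balance, called 0, 4 and 5 for the strains at 15 mM, 25 mM and on average, 7 and 7 for 25 against 15 mM in TMB3400 and FT30-3, 8 for 36 against 25 mM and 0 for the interaction. It was run before centring, so its dose calls may include lists that only follow the general rise. Quantile normalization gave 9 for the strains at 25 mM, leaving out chromosome XVI gave 20 for the mean strain difference, and leaving out dim probe sets gave 11 for the interaction. The cause was not tested.

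With the replicate number as a block, 73 genes passed for the strains at 15 mM and 11 lists for the interaction. The block moved no other number of genes or lists by more than 1.5 times. Of 382 results of named genes, 48 lost their call under it, among them YJL136W-A (adjusted p = 0.0979), YNL042W-B (0.15), YGR153W (0.067) and YER078W-A (0.0979) in the interaction, and 1 gained it, ARI1 in the mean strain difference (0.0265). Nothing in the labels used here says what a number stands for, and same-number samples did not all deviate together, so the numbers were not taken as pairs over all groups. Of 23 such pairs, 13 had deviations correlated over 0.1 (-0.394 to 0.579, with a median of 0.19). The median was -0.12 for 44 pairs with other numbers, and 7 of 13 samples correlated best with their own number. Deviations sum to 0 within a group, so the pairs are not independent. Positive values for same numbers also force negative ones for other numbers, so -0.12 is no separate evidence. As noticed after these values were seen, the 10 pairs with a sample of FT30-3 at 15 mM lay between -0.394 and 0.063 and the 13 others between 0.188 and 0.579, so the number went with shared deviations among the other 4 groups. Replicate 2 of FT30-3 at 15 mM correlated at 0.304 to 0.46 with replicate 1 of every other group. With replicate 2 of those groups it correlated at -0.37 to -0.117. The numbers of that group may therefore be in another order, which was not tested. The block over all groups may then place its samples wrongly, and the values from that block are uncertain. A fit of the 4 groups other than FT30-3 at 15 mM gave, with the block and without it, 343 and 245 genes for the strains at 25 mM, 103 and 67 for 25 against 15 mM in TMB3400, and 518 and 240 for 36 against 25 mM. With that block, 19 results of named genes lost their call, among them ADH6 at 25 mM (adjusted p = 0.0576), and without it 31 did.

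Leaving out 1 sample at a time, which can leave a group with 1 sample assumed to vary like the others, gave these ranges of genes. For the strains they were 7 (TMB3400 at 15 mM replicate 2 left out) to 258 at 15 mM, 121 (FT30-3 at 25 mM replicate 1) to 584 at 25 mM and 341 (TMB3400 at 15 mM replicate 1) to 985 on average. For 25 against 15 mM they were 36 (TMB3400 at 15 mM replicate 1) to 367 in TMB3400 and 85 (FT30-3 at 25 mM replicate 1) to 440 in FT30-3. For 36 mM they were 1293 (FT30-3 at 15 mM replicate 2) to 1754 against 15 mM and 119 (FT30-3 at 25 mM replicate 1) to 412 against 25 mM, and for the interaction 22 (TMB3400 at 15 mM replicate 2) to 51. Leaving out FT30-3 at 36 mM replicate 1 gave the highest number of genes in the 3 strain comparisons, both comparisons of 25 with 15 mM, 36 against 25 mM and the interaction. Apart from 36 against 25 mM, these comparisons do not use that array. It changed their counts only through the spread shared by all groups. Lists ranged from 2 to 12, 7 to 15 and 9 to 14 for the strains, 12 to 18 and 10 to 17 for 25 against 15 mM in TMB3400 and FT30-3, 16 to 18 and 12 to 18 for 36 against 15 and 25 mM, and 4 to 12 for the interaction.

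Of 9275 alternatives for 382 results of named genes, 8084 kept direction and call, 1141 lost the call, 20 gained it and 30 changed sign, in 11 results. None of the 11 passed in either setting, and the cause was not tested. Quantile normalization gave 0 for GRE3, 0.027 for TKL1 and 0.014 for TAL1 in the strains at 25 mM, and 0.031 for ZWF1, 0.05 for TAL1 and 0.012 for ALD6 in the interaction. Array weights gave 0.011 for TKL1 at 25 mM, and 0.003 for ZWF1 and 0.011 for ALD6 in the interaction. Leaving out 1 sample at a time, the ranges that include a change of sign were, for GRE3, -0.164 to 0.048 at 15 mM, -0.212 to 0.133 at 25 mM, -0.144 to 0.028 on average and -0.136 to 0.208 in the interaction, where FT30-3 at 15 mM replicate 2 (-0.087) also turned it, as it did the average (0.004). At 25 mM they were -0.24 to 0.005 for ZWF1, -0.043 to 0.02 for TKL1 (0.007 in another) and -0.108 to 0.006 for TAL1. In the interaction they were -0.151 to 0.094 for ZWF1 (also 0.045 and 0.036), -0.058 to 0.055 for TAL1 (also 0.011, 0.017 and 0.007), -0.051 to 0.018 for ALD6 (also 0.01 and 0.003) and -0.11 to 0.206 for XKS1. Signal over background limits the dim genes: 79 probe sets had a mean below the S. pombe 95th percentile.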

Other observations

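Members of 3 other lists changed in FT30-3 between 15 and 36 mM, although no list passed as a whole with an estimated correlation. Of 24 drug efflux genes, 7 rose and 1 fell after centring, and 16 and 1 adjusted over the list alone before it (adjusted p = 0.71 with an estimated correlation). RTA1 rose by 1.42 ± 0.19 and ICT1 by 1.27 ± 0.19, while PDR12, a pump for weak organic acids, fell by 1.81 on the log2 scale. Of 23 general stress genes, 12 fell after centring, and 8 fell and 1 rose adjusted over the list alone before it (adjusted p = 0.36 with an estimated correlation), including the catalase gene CTT1 (-0.91 ± 0.16). In the respiratory chain, 10 of 22 fell after centring and 1 adjusted over the list alone before it (adjusted p = 0.24 with an estimated correlation), including CYB2 (-1.84 ± 0.17), a lactate dehydrogenase. With the preset correlation, the adjusted p of these 3 lists were 0.048, 3.92e-07 and 6.6e-06.

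The tests of other splits of the samples were fixed before their results were seen. Within dose, only the real split of the strains, 1 of 100, gave as many genes as the 586 called. The highest other gave 48, so random assignment of samples to strains can be excluded for that count. The shift of chromosome XVI, which holds 258 of the 390 higher genes, separates all samples by strain. That shift by itself favours the real split, although 132 higher and 196 lower genes lie elsewhere. No split was run without that chromosome, so the result is not evidence gene by gene. Splits that mix the strains also put any real difference between the groups into the spread, which lowers their counts. The test cannot tell a strain effect from a difference between sets of arrays, since such sets may coincide with the strains at the higher dose averaged. For lists, 42 of 100 splits gave at least the 12 called, and the highest other gave 19, so chance cannot be excluded. For 36 against 15 mM the 10 splits are too few for a share under 0.05: the real split called 1752 genes and the highest other 0, with 1 split as large, and for lists the real split called 17 and the highest other 20, with 2 splits as large.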
